A study of Mus musculus with 12 samples.

How the data were processed

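RNA was measured in 12 libraries from CD4 T effector cells, in 4 groups of 3: islet and spleen of recipients of WT origin cells, and islet and spleen of recipients of Y16A origin cells. Per the labels' protocols, splenocytes of immunised female mice of 6 to 8 weeks were expanded for 2 weeks with 10 µM peptide. The purified CD4 T cells were over 95% pure with under 1% Foxp3-positive cells, and female NOD.scid recipients of 8 to 10 weeks received them. Cells were lysed in Triton X-100, and the RNA was reverse transcribed, amplified and made into libraries with Nextera XT, per the labels' protocols. These protocols describe a purification before transfer and name no sort of the cells taken from the recipients. The sample titles read pancreas for the libraries called islet here. The genotype entry of the sample labels gives NOD for every islet and NOD.Y16A for every spleen library, which goes against the sample titles and the design text; the titles and design text were used for the groups.

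The authors aligned reads with TopHat 1.0.0 and computed FPKM with Cufflinks on mm9, per the submitters' processing notes. The deposited matrix holds FPKM per transcript and library. The authors' deposited table gives FPKM per condition with p-values and q-values for islet Y16A against islet WT, and 99.83% of its 9763 entries with a gene in the reference overlap that gene on GRCm38, although the notes name mm9; 1 emptied line of that table is not used here. The planned count tests were replaced by the planned FPKM test, since the matrix used here holds FPKM. Of 36285 entries of the matrix (35685 unique accessions, 905 entries with a repeated accession), 99.16% (35981) matched a gene symbol, and the FPKM of a gene's transcripts were summed to 24563 genes, of which 5733 were 0 in every library. No entry of the matrix names a variable segment of a T cell receptor gene, so clones were not analysed here.

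Depth was estimated from the FPKM steps of transcripts with few fragments: 4.28 to 8.27 M mapped fragments per library (islet WT 5.39 to 7.4, islet Y16A 5.3 to 8.27, spleen WT 4.78 to 7.47, spleen Y16A 4.28 to 7.69). At this depth 3 fragments on a transcript of 1500 bp correspond to 0.242 to 0.467 FPKM. The FPKM totals ran from 163868 (spleen WT 1) to 342434 (islet WT 3).

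Genes with at least 1 FPKM in at least 3 libraries were tested (10115) as log2(FPKM + 1) in limma 3.58.1 (R 4.3.3, statmod 1.5.0), with a model of 4 group means, 8 residual degrees of freedom and empirical Bayes moderation with an intensity trend and robust variance. The contrasts were islet against spleen within each origin, Y16A against WT within each tissue, and their difference (the interaction). Adjusted p values are Benjamini-Hochberg values, and a gene was called at an adjusted p under 0.05. Printed log2 changes are relative to the median change of genes with mean above 5 FPKM, which was 0.156 (islet against spleen, WT), 0.324 (the same, Y16A), 0.255 (Y16A against WT, islet), 0.076 (the same, spleen) and 0.164 (interaction), while p values belong to the fit without this subtraction. The median standard error was 0.332 for genes with mean above 50 FPKM. The pipeline was tested on simulated data with 5 runs of 10115 genes and 100 changed genes per fold. The share of false calls was 4.55% (islet against spleen, WT) and 7.67% (Y16A against WT, islet). Camera called 5 of 5 changed sets and 0 of 5 unchanged sets. Changes were planted only in genes with higher mean values. Residuals were shuffled separately for each gene, so the simulated genes were not correlated. The set counts therefore do not test the preset correlation.

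Gene lists were 21 function lists and 9 marker lists of other cells, tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast, where at least 5 members were tested (28 of 30 lists). B cell markers (1 tested, highest Cd79b at 7.6 FPKM) and endothelial and stromal markers (4 tested, highest Mgp at 21.4 FPKM) had too few tested members. A second adjustment was made over the members of each list alone. Camera with an estimated correlation and fry, directional and mixed, were alternatives. Genes were named by rule: among called genes with a mean of 5 FPKM or more and non-overlapping values, the 10 with the largest log2 change in each direction, filled to 5 by smallest p where fewer passed; up to 4 members of each list with the smallest p; and a fixed set of genes of interest. Unnamed gene models and small RNA genes were passed over by this rule. Members of lists that are named without values, and genes singled out in the observations, were chosen after their values were seen. The tests, contrasts, lists, naming rule and most alternatives were chosen before the data were examined; the transcript-level fit, the fit without islet WT 1 and 2 and a fit with the endocrine marker level as a covariate were added after.

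The sample titles name the same mouse for an islet and a spleen library, so the mouse pairs the tissues; the correlation of the deviations from the group means was -0.016 to 0.099 within a mouse and -0.114 to 0.028 between mice. Mouse was not in the planned model and entered as a block in an alternative, whose count of calls is given beside each tissue comparison (89 and 135). Other alternatives were quantile normalization and median centring, array weights, pseudocounts of 0.1 and 5, no filter and a filter of 5 FPKM in 3 libraries, a fit of only 2 groups, marker genes left out, a threshold of 1.5-fold (treat), and leaving out each library in turn. The group labels were also permuted over 10 splits of 3 against 3, where the smallest possible share is 0.1, and 100 drawn splits for the interaction. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.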

Results

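The libraries came from insulin-reactive CD4 T effector cells taken back from pancreatic islets and spleen after transfer into NOD.scid recipients, a strain without T cells of its own. Per the labels, the donors were female NOD mice (WT origin), which develop autoimmune diabetes, or female NOD.InsY16A transgenic mice (Y16A origin). The cells had been expanded on an insulin peptide before transfer. There were 3 recipients per origin, each giving 1 islet and 1 spleen library, so 4 groups of 3 libraries were compared. After filtering, 10115 genes were tested, and each library listed 7464 to 8687 genes at 1 FPKM or more. The replicates differed a good deal from each other: across genes, the correlation of log2 values between libraries of the same group was 0.827 to 0.900 (median 0.862), against a median of 0.861 for the same tissue and other origin and 0.829 for the other tissue. Genes are not independent replicates, and these correlations describe similarity only. The principal components held 22.4%, 13.1% and 9.1% of the variance. Values below are mean FPKM ± SD over 3 libraries (n = 3), and where a library of the group was listed at 0 its 3 values are given instead.

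Islet and spleen cells of WT origin differed in activation and effector genes. Ifng, the cytokine of type 1 helper cells, was higher in the islet libraries (144 ± 33.9 against 7.78 ± 5.12, log2 change 4.02, SE 0.44, adjusted p 1.1e-05). So was Rgs1, a regulator of chemokine receptor signalling that is high in tissue-resident T cells (211 ± 63.8 against 7.43 ± 5.62, log2 change 4.81, SE 0.55, adjusted p 3.47e-05). Ctla4, an inhibitory receptor induced by T cell activation, rose as well (38.2 ± 12.9 against 6.51 ± 2.55, log2 change 2.23, SE 0.40, adjusted p 0.00315). Genes of recirculation through lymphoid tissue fell, among them the lymph node homing receptor Ccr7 (9.79 ± 5.56 against 53.2 ± 8.6, log2 change -2.63, SE 0.45, adjusted p 0.00673). Transcripts of Cd3e, a chain of the T cell receptor complex, were high in both tissues and did not pass (323 ± 84.6 against 256 ± 47.4, log2 change 0.16, adjusted p 0.835). In total limma called 82 genes, 64 higher and 18 lower in islet, and 875 had an unadjusted p under 0.05. The 3 islet values lay wholly above or below the 3 spleen values for 1149 genes (11.36%), against 10% expected by chance.

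The largest changes were transcripts of exocrine pancreas. Clps, the pancreatic colipase, had 590.1 ± 407 against 0, 0 and 1.04, log2 change 8.50, SE 0.46, adjusted p 4.84e-09. Of 19 tested acinar and duct markers, 17 were higher and 0 lower, and 19 rose when adjusted over the list alone (camera adjusted p 3.74e-75, or 0.00629 with an estimated correlation). Other genes among the 10 largest rises were the elastase Cela2a (249.5 ± 184, listed at 0 in spleen) and the secreted lectin-like Reg2 (138 ± 43.7, listed at 0 in spleen) and Reg1 (198 ± 117 against 0, 0 and 0.336, log2 change 7.19). They also held the lipase Pnlip (115 ± 85.3, listed at 0 in spleen) and the ribonuclease Rnase1 (109 ± 61, listed at 0 in spleen), and the chymotrypsinogen Ctrb1 (411 ± 333 against 0, 0.168 and 0.463, log2 change 7.95). The trypsinogens Try4, Try5 and Prss2 and the Reg genes are close relatives that can share reads, so the level of each copy is uncertain, although all were near 0 in spleen. No list other than the acinar list holds these 19 genes. Mean log2 acinar marker levels were 5.39 to 7.28 in the islet libraries of WT origin and 0.15 to 0.42 in all spleen libraries. Endocrine markers also rose as a list (1 of 9 higher, Iapp, listed at 0 in spleen, adjusted p 0.0059; 4 adjusted over the list alone; camera adjusted p 0.000176, or 0.105 with an estimated correlation).

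**Figure D1:**
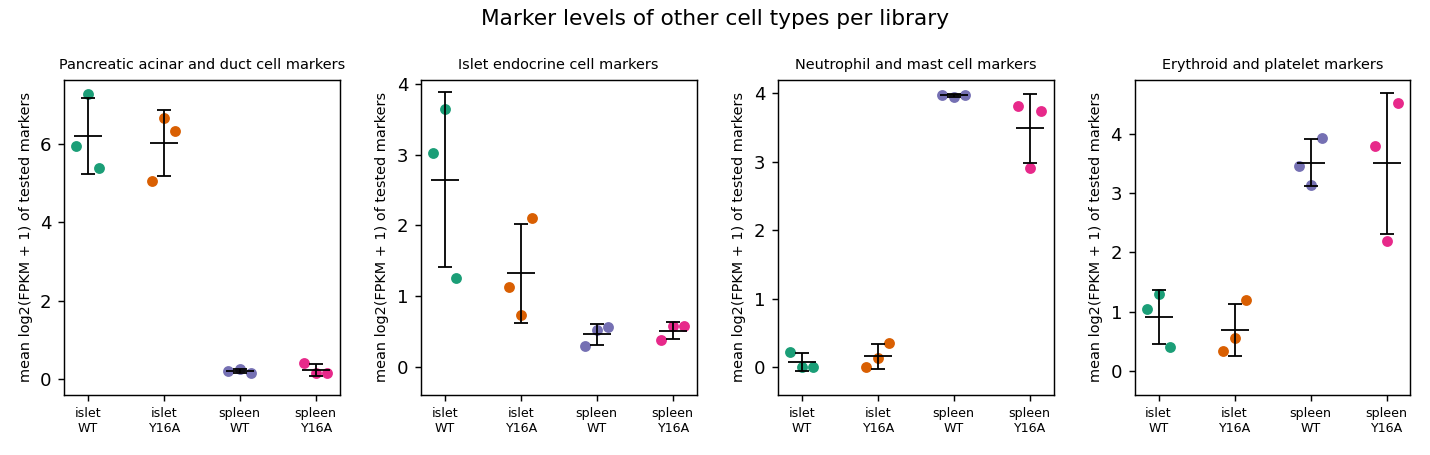
Mean log2(FPKM + 1) of the tested markers of 4 other cell types in each of the 12 libraries. Points are single libraries, and bars give the group mean and SD.

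Immediate early and heat shock genes rose together, 8 of 23 higher and 0 lower in islet, and 16 when adjusted over the list alone (camera adjusted p 3.06e-28, or 0.0122 with an estimated correlation). They included the AP-1 member Fos (128 ± 68.1 against 1.59 ± 0.646, log2 change 5.39, SE 0.42, adjusted p 1.3e-07) and the phosphatase gene Dusp1 (90.0 ± 28.2 against 0, 0 and 0.452, log2 change 6.13). Hspa1a and Hspa1b, inducible heat shock genes with nearly identical sequence, were both called, and the split between the copies is uncertain. Of 20 TCR-induced activation genes, 4 were higher and 0 lower, and 8 rose adjusted over the list alone (camera adjusted p 4.4e-10, or 0.105 with an estimated correlation). Besides Ctla4 these were the nuclear receptor Nr4a1 (66.8 ± 44.7 against 6.63 ± 3.89, log2 change 2.97, SE 0.58, adjusted p 0.00837), the early activation marker Cd69 (79.5 ± 30.9 against 18.9 ± 2.33, log2 change 1.80) and the NF-kappaB inhibitor Nfkbia (226 ± 71.3 against 63.8 ± 24.6, log2 change 1.69). Tissue residency genes rose (3 of 14 higher, 0 lower, 7 over the list alone; camera adjusted p 4.37e-09, or 0.0214 with an estimated correlation). They held the transcription factor Bhlhe40 (80.7 ± 10.9 against 20.8 ± 6.89, log2 change 1.80) beside Rgs1 and Cd69. Th1 and cytotoxic effector genes rose too (3 of 23 higher, 0 lower, 5 over the list alone; camera adjusted p 2.52e-05, or 0.377 with an estimated correlation). The called members were Ifng and the chemokines Ccl4 (400.4 ± 86.7 against 43.6 ± 19.1, log2 change 3.07, SE 0.51, adjusted p 0.00277) and Ccl5 (3786 ± 964 against 997 ± 432, log2 change 1.85).

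On the lower side stood naive and central memory genes, with 3 of 16 lower (Ccr7 and Dapl1 among them) and 0 higher, and 7 lower over the list alone (camera adjusted p 3.52e-11, or 0.0405 with an estimated correlation). Fut7, a fucosyltransferase, fell (1.63 ± 1.01 against 22.8 ± 9.05, log2 change -3.32, SE 0.46, adjusted p 0.000602). The pseudokinase gene Trib2 (7.84 ± 1.98 against 44.6 ± 19.1, log2 change -2.46) and the Notch pathway regulator Dtx1 (4.15 ± 1.59 against 24.9 ± 11.1, log2 change -2.43) fell too. Also lower were the carbonic anhydrase Car2, which is on the erythroid marker list (1.03 ± 0.82 against 14.5 ± 5.24, log2 change -3.12), and the tubulin-binding Tppp3 (0, 2.46 and 5.08 against 16.5 ± 4.32, log2 change -2.79). Markers of other blood cells were part of the spleen side, and their source was not tested. Of 5 tested neutrophil markers 3 were lower in islet, S100a8 and S100a9, the calprotectin subunits, and the antimicrobial peptide gene Camp. All 5 fell over the list alone (camera adjusted p 1.2e-16, or 0.000649 with an estimated correlation). S100a8 was listed at 0 in the islet libraries against 91.7 ± 50.6, and S100a9 at 0 against 63.8 ± 41.5. Of 9 erythroid and platelet markers 2 were lower and 4 over the list alone (camera adjusted p 8.76e-10, or 0.0175 with an estimated correlation), where the globin copies Hbb-b1 and Hbb-b2 share reads and are uncertain. The 1 lower gene of 7 dendritic cell markers was Ccr7, which the naive list also holds (camera adjusted p 0.0292, or 0.152 with an estimated correlation).

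Smaller list shifts in WT origin were mostly upward. Inhibitory receptor genes (1 of 16 higher, Ctla4; 6 over the list alone; camera adjusted p 0.00057, or 0.201 with an estimated correlation) rose. So did apoptosis and survival genes (1 of 18, Bcl2a1b; 2 over the list alone; 0.000594, or 0.201) and regulatory T cell genes (1 of 14, Ctla4; 3 over the list alone; 0.0316, or 0.377). Ribosomal protein genes (0 of 31 called, camera adjusted p 3.46e-07, or 0.201 with an estimated correlation) and cell cycle genes (0 of 31, 0.00126, or 0.377) rose as lists without any called member. The other 13 lists did not pass: oxidative phosphorylation (0.0811), macrophage (0.112), unfolded protein response (0.393), interferon gamma response (0.412), type I interferon (0.43), Th2 and Th17, glycolysis and T follicular helper (0.84 each). At higher values were NK and CD8 cell markers and chemokine receptors (0.847 each), T cell receptor complex and anergy (0.875 each) and cholesterol synthesis (0.905). With quantile normalization the T cell receptor complex list turned direction and passed as lower in islet (0.0262). By directional fry 7 lists that camera passed did not pass. They were inhibitory receptor (fry adjusted p 0.0628), apoptosis (0.0698), ribosomal protein (0.0868) and regulatory T cell (0.111). The others were dendritic cell (0.124), Th1 and cytotoxic (0.142) and cell cycle (0.167). Among chemokine receptors Cxcr4 was higher (12.8 ± 6.71 against 0.865 ± 0.0878, log2 change 2.62), while Cxcr6, which guides T cells into inflamed tissue, did not pass (adjusted p 0.0614). With the mouse as a block, which pairs the tissues of a recipient, the count was 89, with 75 of the 82 calls kept. Of the genes named by rule and the lists, Pdcd1 (adjusted p 0.023), Nkg7 (0.0134), Csf2 (0.0267), Rps14 (0.0256), Gcg (0.0265), Hbb-b1 (0.000645) and the oxidative phosphorylation list (0.0405) passed and Tppp3 (0.0665) did not.

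Leaving out islet WT 2 ended the call of Ccr7 (adjusted p 0.0532), and leaving out islet WT 3 those of Cd69, Nr4a1 and Cxcr4 (0.0586, 0.0702 and 0.0529). Camp, Car2, Dapl1, Dtx1, Hbb-b2, Tppp3 and Trib2 were each lost without at least 1 of the 6 libraries (islet WT 1, 2 and 3, spleen WT 1, 2 and 3; adjusted p 0.0529 to 0.176). So were the dendritic cell (0.0753 to 0.117), regulatory T cell (0.0572 to 0.26) and cell cycle (0.0701) lists. With quantile normalization 107 genes were called, 69 higher and 38 lower.

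Islet and spleen cells of Y16A origin showed the same kind of difference. Ctla4 was higher in islet (81.9 ± 23 against 4.45 ± 1.22, log2 change 3.60, SE 0.40, adjusted p 7.55e-06), and so was Ifng (200.5 ± 91.2 against 9.66 ± 3.69, log2 change 3.89, SE 0.44, adjusted p 1.02e-05). The chemokine receptor Ccr8, found on activated and skin-homing T cells, rose (85 ± 22.7 against 8.76 ± 4.2, log2 change 2.88, SE 0.41, adjusted p 0.000136), as did Rgs1 (312 ± 52.8 against 16.8 ± 8.18, log2 change 3.92, SE 0.55, adjusted p 0.000204). Ccr7 fell (7.58 ± 3.79 against 51.1 ± 6.92, log2 change -3.02, SE 0.45, adjusted p 0.0024). Here limma called 118 genes, 98 higher and 20 lower, and 1025 had an unadjusted p under 0.05. The islet and spleen values did not overlap for 1848 genes (18.27%), against 10% by chance. With quantile normalization 122 genes were called, 73 higher and 49 lower, as with median centring.

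Of 23 immediate early and heat shock genes 13 were higher and 0 lower, and 19 over the list alone (camera adjusted p 1.42e-33, or 0.0079 with an estimated correlation). They were led by Fos (253 ± 30.1 against 0.731 ± 0.539, log2 change 6.92, SE 0.42, adjusted p 1.16e-08), Dusp1 (154 ± 24.6 against 0, 0 and 1.78, log2 change 6.45) and Hspa1a (217 ± 78.5 against 0.997 ± 0.793, log2 change 6.46; the split with Hspa1b is uncertain). Of 20 TCR-induced genes 8 were higher, 0 lower, and 13 over the list alone (camera adjusted p 5.3e-17, or 0.0281 with an estimated correlation). These included Nr4a1 (111 ± 43.6 against 4.34 ± 2.92, log2 change 4.15, SE 0.58, adjusted p 0.000166), Cd69 (88.4 ± 14.1 against 16.5 ± 7.42, log2 change 2.09, SE 0.37, adjusted p 0.000943) and the costimulatory receptor Tnfrsf4 (210.0 ± 20.6 against 63.4 ± 8.69, log2 change 1.39, SE 0.26, adjusted p 0.000963). The others were Ctla4, Nr4a2, Dusp2, Nfkbia and Nfkbid. Tissue residency genes rose (6 of 14 higher, 0 lower, 7 over the list alone; camera adjusted p 1.77e-08, or 0.0189 with an estimated correlation). Among them were Cxcr6 (342 ± 84.7 against 89.3 ± 27.9, log2 change 1.62), Rgs2 (37.3 ± 11.1 against 3.17 ± 3.31, log2 change 3.25), Bhlhe40 (168 ± 39.4 against 37.3 ± 12.6, log2 change 1.85) and the ATP receptor P2rx7. Th1 and cytotoxic genes rose (3 of 23 higher, 0 lower; 6 higher and 1 lower over the list alone; camera adjusted p 0.000228, or 0.448 with an estimated correlation). They included Ifng and Ccl4 (217 ± 16.6 against 46.4 ± 32.2, log2 change 2.23). The 1 lower over the list alone was the granzyme gene Gzma (21.3 to 28.4 FPKM in islet against 42.7 to 115.4 in spleen).

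Naive and central memory genes fell (3 of 16 lower, 0 higher, 7 lower over the list alone; camera adjusted p 3.13e-15, or 0.0169 with an estimated correlation). They included Dapl1 (listed at 0 in islet against 30.5 ± 22.5) beside Ccr7. Other genes that fell were Fut7 (3.04 ± 0.0605 against 33.5 ± 13.7, log2 change -3.35, SE 0.46, adjusted p 0.000851), Dtx1 (4.26 ± 1.99 against 36.2 ± 4.99, log2 change -3.22) and the erythroid marker Car2 (0, 0.163 and 0.468 against 16.1 ± 12.3, log2 change -3.86). The same held for Magohb, an exon junction complex gene (2.34 ± 1.97 against 21.5 ± 5.75, log2 change -3.25), and Gpr15, a homing receptor for the colon (0, 0.136 and 1.53 against 12.2 ± 6.35, log2 change -3.39). Neutrophil markers (3 of 5 lower, 4 over the list alone; camera adjusted p 7.63e-15, or 0.00106 with an estimated correlation) were lower in islet. So were erythroid and platelet markers (1 of 9 lower, 4 over the list alone; 2.14e-12, or 0.00812) and macrophage markers (1 of 12 lower; 1 higher and 2 lower over the list alone; 5.1e-05, or 0.0102). S100a9 was listed at 0 in the islet libraries against 60.7 ± 11.1, and Tyrobp, an adaptor of myeloid and NK cells, fell (0, 0 and 5.41 against 47.2 ± 23.5, log2 change -4.89, adjusted p 0.00155). Acinar markers were again the largest changes, 16 of 19 higher, 0 lower, and 19 over the list alone (camera adjusted p 5.03e-62, or 0.0079 with an estimated correlation). Examples were Clps (531 ± 124 against 0, 0 and 0.664, log2 change 8.46) and Cela2a (207 ± 131, listed at 0 in spleen). Mean log2 acinar marker levels in the islet libraries of Y16A origin were 5.06 to 6.66.

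Apoptosis and survival genes (2 of 18 higher, Bcl2a1b and Bcl2a1d, copies that share reads and are uncertain; 3 over the list alone; camera adjusted p 0.00537, or 0.377 with an estimated correlation) rose as a list. Inhibitory receptor (2 of 16, Ctla4 and Cd160; 4 over the list alone; 0.00885, or 0.399) and Th2 and Th17 genes (1 of 11; 2 over the list alone; 0.0121, or 0.144) rose likewise. Dendritic cell markers fell (1 of 7, Ccr7; 0.00705, or 0.0699). Lists that passed with 0 called members were ribosomal protein (0.00292, or 0.453), glycolysis (0.00723, or 0.44), cell cycle (0.0222, or 0.557) and oxidative phosphorylation (0.0354, or 0.689). With quantile normalization the oxidative phosphorylation list turned direction and did not pass (0.694). The other 11 did not pass: regulatory T cell (0.0638), NK and CD8 (0.129), T cell receptor complex (0.176), endocrine (0.234), interferon gamma (0.235), cholesterol synthesis (0.496), unfolded protein response (0.516), type I interferon (0.67), chemokine receptors and T follicular helper (0.816 each) and anergy (0.858). By directional fry 5 lists that camera passed did not pass. They were dendritic cell (fry adjusted p 0.0642), Th1 and cytotoxic (0.0848), ribosomal protein and cell cycle (0.139 each) and oxidative phosphorylation (0.213). Regulatory T cell genes passed by fry (0.0374). With the mouse as a block the count was 135, with 107 of the 118 calls kept. Of the genes named by rule and the lists, Pdcd1 (adjusted p 0.0211), Gzma (0.0307), Rplp1 (0.0364), Hbb-b1 (0.000721), Hbb-b2 (0.00488) and the NK and CD8 list (0.0346) passed. Of these genes Gzma, Hbb-b1 and Hbb-b2 were lower in islet. Bcl2a1d (0.0693) and Cd160 (0.087) did not pass. Bcl2a1b, Bcl2a1d, Ccl4, Cd160, Gpr15 and Magohb were each lost without at least 1 of the 6 libraries (islet Y16A 1, 2 and 3, spleen Y16A 1, 2 and 3; adjusted p 0.0527 to 0.193). So were the apoptosis, inhibitory receptor, Th2 and Th17, glycolysis, cell cycle and oxidative phosphorylation lists (0.05 to 0.194).

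The tissue difference was shared by the origins. Of the 64 and 98 genes higher in islet 51 were the same, where 0.62 would be shared if the calls were independent. Of the 18 and 20 lower genes 10 were the same, where 0.04 would be, and 0 genes were called in opposite directions. Both comparisons use the same estimate of each gene's spread, so their calls are not independent. Across genes, the correlation of the log2 changes was 0.441 over all tested genes. It was 0.919 over the 139 called in either origin, which were selected by these same changes. Genes are not independent replicates. Of the 61 shared genes 16 were acinar markers and 21 belonged to any marker list of another cell type. The 16 is a lower bound for products of the exocrine pancreas, since shared genes outside every list, such as Reg2, Rnase1, Sycn, Reg3a, Reg3b and Pla2g1b, are also such products.

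**Figure D2:**
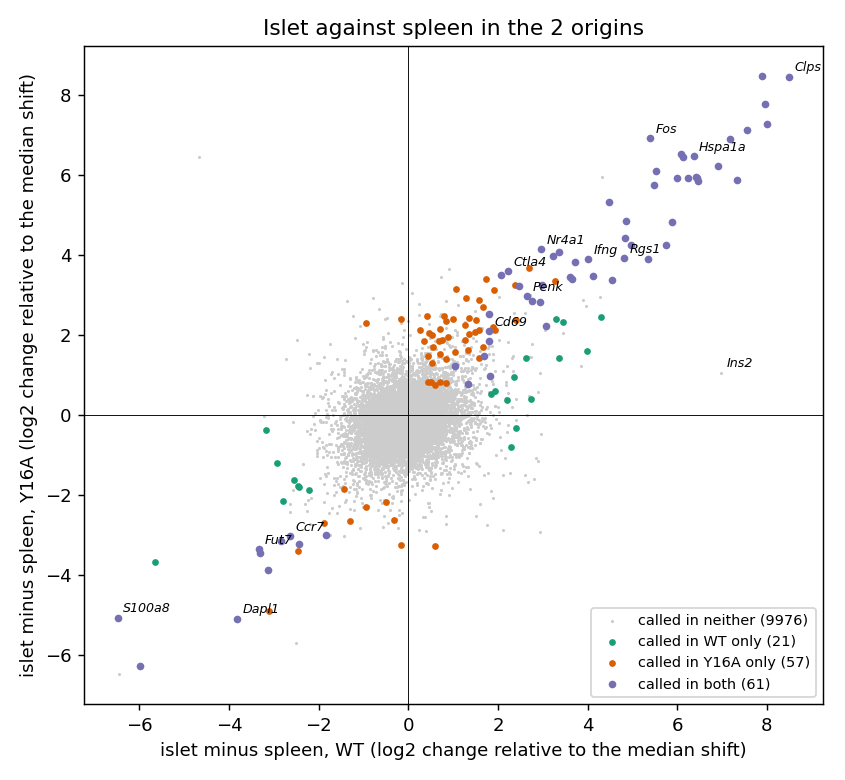
Log2 change between islet and spleen in Y16A origin against WT origin, 1 point per tested gene. Colours mark genes called in neither, either or both origins.

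In the islet, no gene passed between Y16A and WT origin. Magohb, which had the smallest p among the genes with a mean of 5 FPKM or more, did not pass (2.34 ± 1.97 against 22.8 ± 5.54, log2 change -3.27, SE 0.55, adjusted p 0.134). Trat1, an adaptor of the T cell receptor complex (113 ± 35.9 against 32.2 ± 4.89, log2 change 1.48, SE 0.39, adjusted p 0.366), and the glucose transporter Slc2a3 (13 ± 1.9 against 3.73 ± 0.444, log2 change 1.31, SE 0.43, adjusted p 0.758) did not pass. Gmnn, an inhibitor of replication licensing, did not either (14.9 ± 2.28 against 41 ± 7.85, log2 change -1.65, SE 0.43, adjusted p 0.965). The effector and activation genes Ctla4 (81.9 ± 23 against 38.2 ± 12.9, log2 change 0.84, SE 0.40, adjusted p 0.965), Ifng (log2 change 0.15), Nr4a1 (0.57), Bhlhe40 (0.78), Ccl5 (-0.87) and Cd5, whose level follows the strength of T cell receptor signalling (0.06), did not pass. The count by limma was 0, and it stayed 0 with each library left out in turn. Of the 10115 tested genes 478 had an unadjusted p under 0.05, where a share of 0.05 would by chance. Of these, 374 were higher and 104 lower in Y16A origin, in a fit that kept the median change of 0.255. The values of the origins did not overlap for 1015 genes (10.03%), against 10% by chance.

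Camera passed 6 lists here, and for each the adjusted p was 0.5 or more with an estimated correlation. Higher in Y16A origin were immediate early and heat shock genes (adjusted p 0.000328, or 0.654 with an estimated correlation; 0 of 23 called). Examples are Ier2, 140.3 ± 15.1 against 68 ± 28.1, and Junb, 467 ± 81.3 against 251 ± 112. The mean log2 level of this list was 4.64, 4.98 and 5.52 in islet WT 1, 2 and 3. It was 5.51 to 5.67 in the islet Y16A libraries, so the shift followed islet WT 1 and 2. These 2 libraries had the most endocrine transcripts. They also lay below islet WT 3 in other lists, such as T cell receptor complex (5.9 and 6.08 against 6.77). In that list islet WT 3 lay above islet Y16A 2 and 3 (6.48 and 6.49). Th2 and Th17 genes went the other way (2.39 and 2.16 against 1.8 in islet WT 3). Glycolysis genes were also higher in Y16A origin (camera adjusted p 0.00274, or 0.654, with 0 of 18 called and Slc2a3 over the list alone). The same held for T cell receptor complex (0.0184, or 0.673, 0 of 18) and TCR-induced genes (0.0377, or 0.673, 0 of 20). Lower were endocrine markers (0.000831, or 0.5 with an estimated correlation; 0 of 9, and 3 over the list alone, Gcg, Ins2 and Iapp) and acinar markers (0.0111, or 0.673; 0 of 19, and 2 over the list alone, Amy2b and Krt18). The smallest adjusted p of the other set test, fry, was 0.391 in its directional form and 0.0761 (endocrine markers) in its mixed form. Without islet WT 1, islet WT 2 or islet Y16A 1 the endocrine (0.0549 to 0.132), T cell receptor complex (0.133 to 0.239) and TCR-induced (0.0904 to 0.348) lists did not pass, and without islet Y16A 1 glycolysis did not (0.0967). The direction of the acinar list turned without islet WT 2 (0.579) or islet Y16A 1 (0.492). Further lists passed by camera without islet WT 1 (5), islet WT 3 (3), islet Y16A 2 (6) or islet Y16A 3 (1). With quantile normalization 2 further lists passed and 1 was lost.

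The authors' deposited table of their own islet comparison, which tests transcripts and gives 1 value per condition, called 91 of 9815 entries at a q value under 0.05, 36 higher in Y16A origin and 55 higher in WT origin. Of the 91 in the authors' deposited table, 66 were listed at 0 in 1 condition and 25 were above 0 in both. The 10 of these higher in Y16A origin in the authors' deposited table included Fos (412 to 742 FPKM, q 0.00701), Trat1 (118 to 339, q 0.00701), Ctla4 (150 to 282, q 0.0126), Bhlhe40 (279 to 479) and Slc2a3 (14.4 to 40.9, q 0.0289). They also included, in the authors' deposited table, Junb (828 to 1369, q 0.0436) and Btg2 (165 to 283, q 0.0485). The 15 higher in WT origin in the authors' deposited table included Ccl4 (1475 to 679, from WT to Y16A, q 0.00701), Ccl5 (12220 to 6886, q 0.00701) and the acinar gene Cela1 (386 to 102). Of the 25, 24 had an entry in the matrix used here, and 15 of these had the 3 libraries of 1 origin wholly above the 3 of the other in the direction of the authors' deposited table, where 5% would by chance. In the fit of this work 23 of them were tested: all 23 moved in the same direction as in the authors' deposited table, 16 had an unadjusted p under 0.05, and the smallest adjusted p was 0.366. The libraries are the same, so this is no independent test. The values of the authors' deposited table were a median of 3.25 times the matrix means.

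In the spleen, no gene passed between the origins either. Polr2k, a subunit of the RNA polymerases (8.39 ± 4.68, listed at 0 in WT origin, adjusted p 0.307), the cytokine receptor gene Crlf2 (log2 change 2.20, SE 0.60, adjusted p 0.514) and Tnfsf11, the RANK ligand gene (8.6 ± 2.97 against 1.98 ± 2.18, adjusted p 0.571), did not pass. Nor did H2bu2, a histone gene (log2 change -3.21, SE 0.71, adjusted p 0.318), the interferon-induced Oasl2 (-1.83, adjusted p 0.571), or Bola1 (-2.83), Plekhf1 (1.95), Stk16 (-2.68) and Ifng (0.29). The count by limma was 0, with a smallest adjusted p of 0.307. Of the 10115 tested genes 520 had an unadjusted p under 0.05 (325 higher and 195 lower in Y16A origin), where a share of 0.05 would by chance. Values did not overlap for 918 genes (9.08%), against 10% by chance. No list passed (smallest camera adjusted p 0.165), although 1 passed without spleen Y16A 1 and 2 passed without spleen Y16A 3. The count became 1 without spleen WT 2 (Pole3), spleen WT 3 (Snora78), spleen Y16A 2 (Stk16) or spleen Y16A 3 (H2bu2), a different gene each time.

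The origin effect was then compared between islet and spleen, as the interaction of tissue and origin. No gene passed, and the smallest adjusted p by limma was 0.994. Of the 10115 tested genes 433 had an unadjusted p under 0.05 (274 higher and 159 lower), where a share of 0.05 would by chance. Zfp672, a zinc finger gene (log2 difference 3.26, SE 0.84), Ctla4 (1.36, SE 0.57) and Magohb (-3.09) were among the genes with the smallest p values or in the lists, and none passed. Without spleen WT 3 the count was 1 (Snora78). The change of 118 genes in Y16A origin and 82 in WT origin is therefore not shown to be a different response, since the test of that difference called 0. Across genes, the correlation of the origin effects in islet and spleen was 0.04. The median standard error of a log2 change was 0.516 for the comparisons of groups and 0.73 for the interaction. In simulated data, planted changes of 2-fold were recovered in 5.4% of genes and of 4-fold in 53.4% (islet against spleen, WT origin) and 52.4% (Y16A against WT in islet). These changes were planted only in genes with higher mean values, so the shares do not cover weakly expressed genes. An absence of calls therefore leaves room for changes of 4-fold and less in many genes. Recovery in weakly expressed genes was not simulated.

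**Figure D3:**
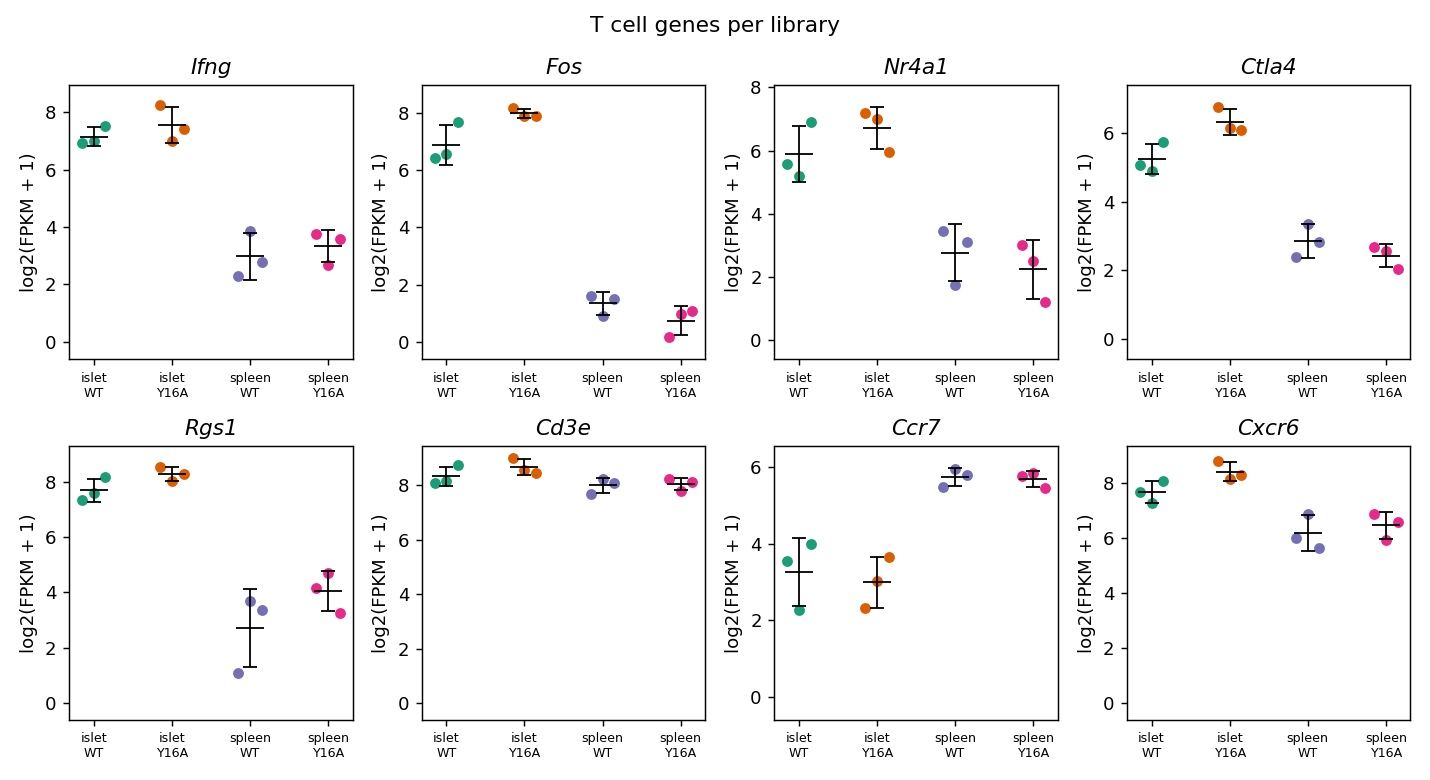
Log2(FPKM + 1) of named genes in each of the 12 libraries. Points are single libraries, and bars give the group mean and SD.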

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

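The tests of explanations in this part were chosen only after the results were seen, except the other splits of the libraries.

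TCR-induced activation genes were higher in Y16A origin in islet relative to spleen (interaction, camera adjusted p 0.031, or 0.968 with an estimated correlation; fry 0.95). No member was called, and Ctla4 had the largest difference in the list (1.36, SE 0.57). The call was lost without islet WT 2, islet Y16A 1, spleen WT 2, spleen WT 3 or spleen Y16A 3 (adjusted p 0.0645 to 0.372).

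Islet libraries of both origins were higher in immediate early, heat shock and TCR-induced genes. RNA of pancreatic acinar cells was examined by slopes over the 6 islet libraries. The 12 members called in both origins had a median slope of -0.34 on the acinar level (-0.66 to -0.01), while acinar markers had 0.92 (0.45 to 1.81). The 12 members share the same 6 libraries, and no standard error was computed. The slopes thus argue against this source without excluding it. Handling of the pancreas could raise the same genes during digestion; 4 TCR-induced members outside the immediate early list were called in both origins (Cd69, Ctla4, Nfkbia and Nr4a1), but stress can also induce Cd69 and Nr4a1. The libraries cannot separate handling from contact with antigen in the islet, because tissue and preparation changed together. The same limit holds for the other genes that differed between islet and spleen, such as Rgs1, Bhlhe40, Ifng and Ccl4.

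Endocrine transcripts stood out in islet WT 1 and 2, with Ins2 at 296 and 878 FPKM against 9.8 in islet WT 3. Endocrine cell RNA in these 2 libraries may be the source. Of 7 endocrine markers other than the insulin genes, 4 (Gcg, Sst, Iapp and Chgb) had their highest islet value there. By chance 2.33 would (exact binomial p 0.1733), so this count cannot decide. The 7 include Nkx6-1, at most 0.2 FPKM in islet, and Scg5, which reached 8.5 FPKM in spleen. More pancreatic tissue of every kind also stays open: the mean log2 acinar level of islet WT 1 was 5.96, inside the 5.06 to 6.66 of the other 4, but that of islet WT 2 was 7.28, the highest of all. Origin of the transferred T cells also stays open: 1 of 9 endocrine markers had all 3 islet WT libraries above all 3 islet Y16A libraries. The mean log2 endocrine level of islet WT 3 was 1.26, inside the 0.73 to 2.1 of the islet Y16A libraries.

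Of the calls in the authors' deposited table, 66 were listed at 0 in 1 condition, 26 in WT and 40 in Y16A, and 20 of them were olfactory, vomeronasal or taste receptor genes. Few fragments in single libraries is a possible source. In the condition with a value, 50 of the 66 transcripts were listed at 0 in a library, and 16 in at least 2. Another 16 of the 66 were above 0 in every library of that condition. Fragments were not counted for the 66 transcripts, so the zeros cannot decide. Origin of the transferred T cells stays open for these transcripts: 2610528A11Rik, listed at 0 in WT in the authors' deposited table, had an adjusted p of 0.355 in the islet fit and 0.0304 with a pseudocount of 0.1.

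Other splits of the libraries were counted for each comparison. For islet against spleen 1 of 10 splits, the true one, reached the count in WT origin (82 calls, highest other 1) and 1 of 10 in Y16A origin (118, highest other 1), and 10 splits cannot give a share under 0.1. Where the true grouping called 0 genes, every split reaches that count by construction, so the counts say nothing about chance: 10 of 10 for Y16A against WT in islet (highest other 2), 10 of 10 in spleen (highest other 3) and 100 of 100 drawn splits for the interaction (highest other 4).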

How the results depend on the processing

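The transcript-level fit, the fit without islet WT 1 and 2 and the fit with the endocrine marker level as a covariate were chosen only after the results were seen. Count-based tests and scalings were not run, because no counts were analysed here. For Y16A against WT in islet the 0 calls became 2 with array weights (Magohb, Rps4l) and 1 with a pseudocount of 0.1 (2610528A11Rik). They became 1 with only the 2 groups (Snora78) and 1 over transcripts (Acly), and stayed 0 with the covariate. In spleen they became 1 with quantile normalization (Snord118), 1 with a pseudocount of 0.1 (Polr2k), 8 over transcripts (among them Ivns1abp, Tysnd1, Puf60, Raly, Zc3hav1, Clec4a3 and Lrmp) and 0 to 1 without a single library. The interaction gave 1 over transcripts (Tor2a) and 0 to 1 without a single library. Leaving out islet WT 1 and 2 leaves 1 islet WT library, so only an effect size is given for that fit. There Spink1 had a log2 change of 6.27 between Y16A and WT in islet, with no median subtracted, against 1.78 with all libraries. Spink1 is on the acinar list. It was listed at 0 in islet WT 3, the WT library kept, and at 52.6 and 209.9 FPKM in islet WT 1 and 2. Islet against spleen in WT origin ranged from 51 (without islet WT 1 and 2) to 110 (array weights), with 54 without marker genes, 57 at a threshold of 1.5-fold, 69 over transcripts, 98 with median centring (72 higher, 26 lower) and 60 to 91 without a single library; in Y16A origin it ranged from 71 (threshold of 1.5-fold) to 171 (array weights), with 79 without a filter, 90 over transcripts and 84 to 96 without a single library. With quantile normalization the T cell receptor complex list in WT origin reversed (adjusted p 0.0262), as did oxidative phosphorylation in Y16A origin (0.694). Lower acinar markers in islets of Y16A origin had adjusted p 1.45e-08 (without islet WT 3) to 0.579 (without islet WT 2, with the direction turned). WT and Y16A libraries share only a number (correlation of same-numbered libraries -0.077 to 0.099). That replicate block gave 0 and 0 calls for islet and spleen and an adjusted p of 0.0501 for TCR-induced genes in islet. The interaction was fitted with the mouse block and also gave 0 calls. The mouse block (89 and 135 calls) kept 75 of 82 and 107 of 118, and among the lists and the genes named by rule changed no call beyond those given with the tissue comparisons.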

Other observations

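The genes in this part were chosen only after the results were seen. Of the genes called in both origins outside every list, the most raised were exocrine pancreas genes, Reg2, Rnase1, Sycn and Reg3b, all listed at 0 in spleen of WT origin (islet means of 138 and 141 FPKM in WT and Y16A origin for Reg2 and 109 and 79.9 FPKM for Rnase1). The Reg copies can share reads and are uncertain. Others were Penk, the enkephalin precursor, higher in islet (159 ± 57.0 against 22.2 ± 8.83 FPKM in WT origin, log2 change 2.66; 288 ± 91.3 against 30.2 ± 16.8 in Y16A origin, 2.98), and the negative regulators of NF-kappaB and G protein signalling Tnfaip3 (3.37 and 4.08) and Rgs16 (2.99 and 3.25). The stress gene Gadd45b (3.22 and 3.97), Phlda1 (2.06 and 3.51) and Ctsw, a cathepsin of cytotoxic lymphocytes (1.05 and 1.23), rose as well. Ifitm1, an interferon-induced membrane protein gene, fell (139 ± 19.8 against 479 ± 235 in WT origin, log2 change -1.83; 69.8 ± 7.37 against 472 ± 166 in Y16A origin, -3.00). Of the 61 genes called in both origins 21 were in no list.

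The Y-linked gene Eif2s3y was above 0 in 12 of 12 libraries (1.1 to 12.0 FPKM). The Y-linked Ddx3y (0 to 3.7) and Kdm5d (0 to 1.7) were above 0 in 11 libraries each, and Uty (0 to 1.4) in 7. Xist ran from 0 to 1.0, while the labels give female donors and recipients. Gapdh was listed at 0 to 1.9 FPKM. The labels do not say whether reads that align to several places were left out of the matrix, so the levels of Gapdh and other multi-copy genes, ribosomal protein genes included, are uncertain. Il17a was listed at 0 in all 12 libraries.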
